A study of Mus musculus with 8 samples.

How the data were processed

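Bulk RNA sequencing was done on the mouse melanoma cell line B16F10. Per the labels, the cells carried either the empty hairpin vector pLKO or a hairpin against Drg2 (shDRG2), and were left unstimulated or given interferon-gamma (IFN-γ) at 5 ng/ml for 24 hours. The 4 groups hold 2 libraries each, 8 libraries in all, and every column of the deposited table was matched to 1 library by its line, treatment and replicate number. The labels describe RNA with an integrity number above 8.5, 1.0 µg of RNA per library and a TruSeq RNA kit. The protocol text states both paired 100-base reads on a HiSeq 1500 and 150-base reads on a HiSeq 2500, and does not say which library was read on which. Library strandedness, the hairpin sequence and whether the replicates were separate cultures are not stated.

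The values the authors deposited are estimated counts (expected counts) of reads per gene, not normalised between libraries. Per the submitters' processing notes the upstream tools were STAR and Salmon 1.5.2 with the mm10 genome, with no role or order given. The gene-level summary tool and the annotation release are not given in the sources used here. Of the nonzero values, 86.4% were whole numbers to within 0.0015, and the others were fractions. Column totals ran from 25422758 to 36654519 counts. The table has 45583 entries, of which 27 carry gene names turned into dates by spreadsheet software, with 2 of those names used more than once. These entries held between 0.204% and 0.212% of the counts of a library and were left out, which left 45556 named genes. Positions came from GENCODE mouse release M21 (GRCm38, the same assembly as mm10), which matched 41827 of 45581 distinct names, or 91.8%, to 1 gene each.

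Counts were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr over the 4 groups, which left 13500 genes. Libraries were scaled by TMM, with factors between 0.973 and 1.04. A quasi-likelihood negative binomial model with 1 coefficient per group and no batch or pairing term was fitted to all 8 libraries, with 4 residual degrees of freedom and a prior of 6.10. The common biological coefficient of variation was 8.49%. The 5 comparisons were shDRG2 against pLKO without IFN-γ, the same with IFN-γ, IFN-γ against none in pLKO cells, the same in shDRG2 cells, and the difference between the 2 IFN-γ responses. Each used the edgeR quasi-likelihood F test, which is two-sided, with Benjamini-Hochberg adjustment over the 13500 genes at 0.05. Unless said otherwise, adjusted p-values are from this test, fold changes are on the log2 scale from this fit, SE is the standard error of that fold change, and n = 2 libraries per group. Expression is in CPM, the count scaled to the TMM-adjusted library size, given as mean ± SD.

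Where every library of a group had 0 counts, a fold is given as a lower bound against a floor of 3 counts over the group. With 1 to 3 counts the ratio is given with its 95% counting interval. Such bounds and intervals cover counting error only, since reads were counted without molecular identifiers. Between replicates, the spread was 11.9 to 16.0 times the counting variance over the genes compared, so depth was not the main limit for well expressed genes. The correlation of log CPM across genes between replicates was 0.992 or 0.993 in each group. On simulated counts with the spread of these data, the same procedure recovered 50.5% of true 1.5-fold changes and 81.8% of true 2-fold changes for the knockdown without IFN-γ, with 11 false calls among 13284 genes. For the difference between responses it recovered 24.0% and 67.7%, with 6 false calls among 13288 genes. The true changes recovered numbered 50 and 81 for the knockdown without IFN-γ, and 24 and 65 for the difference. The knockdown with IFN-γ gave 59 and 75, with 14 false calls. IFN-γ gave 60 and 83 with 14 false calls in pLKO cells, and 59 and 82 with 15 in shDRG2 cells. In every one of these simulations, false calls were a larger share of the calls than the adjusted threshold aims for.

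The comparisons, the tests, the alternatives, the gene lists and the rule for naming genes were fixed before the data were examined. The 28 lists cover DRG proteins and partners, IFN-γ signalling, guanylate-binding and immunity-related GTPases, MHC class I and II presentation, type I interferon-stimulated genes, chemokines and cytokines, checkpoint ligands, PD-L1 trafficking and turnover, endosomes and Rab GTPases, lysosomes, pigmentation, dedifferentiation and invasion, S phase, G2/M, p53 targets, NF-κB targets, the unfolded protein and integrated stress response, hypoxia and glycolysis, cholesterol synthesis, mitochondrial fission and fusion, mitochondrially encoded mRNAs, immediate-early and heat shock genes, replication-dependent histones, and markers of immune, fibroblast, endothelial and epithelial cells. Some genes stand in more than 1 list. Each list was tested against all other genes with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists within a comparison. Camera with an estimated correlation and the self-contained test fry were run beside it.

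Drg2 and Cd274 are named in every comparison. Further names are the 8 largest rises and the 8 largest falls among called genes with a mean of at least 5 CPM and no overlap between the libraries compared, without predicted genes. From each list come up to 4 called members of at least 1 CPM with the largest changes, or, where none was called, up to 2 of the most abundant members. Predicted genes passed over among the largest changes numbered 1 higher and 2 lower for the knockdown without IFN-γ, 1 and 1 with IFN-γ, 1 and 1 for IFN-γ in pLKO cells, and 3 and 0 in shDRG2 cells. Near copies of named genes were searched with blastn 2.17.0 at 95% identity, and exon overlaps were taken from the annotation.

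Each result was recomputed with RLE, upper-quartile and library-size scaling, without a filter, with a filter of 1 CPM in 4 libraries, with DESeq2 1.42.0, with limma-voom, with an added threshold of 1 on the log2 fold change, with only the 4 libraries compared, with the replicate number as a block, and without each library in turn. Leaving out the genes of chromosome 14, and taking the slope between responses only over genes with more than 3 counts in every group, were chosen after seeing the data, as were the comparisons by chromosome. The values of some single genes are not reported here.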

Results

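The data are gene expression profiles of B16F10 mouse melanoma cells, a line that grows in C57BL/6 mice and is widely used to study responses to immune checkpoint blockade. Cells with the empty vector pLKO or with a hairpin against Drg2 were compared without stimulation and after 24 hours of IFN-γ, with 2 libraries in each of the 4 groups. Drg2 encodes a developmentally regulated GTP-binding protein. Library totals were 32855974 and 30813905 counts for pLKO, 27582297 and 32814097 for pLKO with IFN-γ, 32564511 and 25422758 for shDRG2, and 30935756 and 36654519 for shDRG2 with IFN-γ. Mitochondrially encoded transcripts took 3.78% to 5.28% of the counts of a library, and its 10 most abundant genes took 5.19% to 6.47%. The first principal component of log CPM held 79.1% of the variance and the second 8.62%. The third, with 4.15%, placed replicate 1 above and replicate 2 below 0 in each of the 4 groups. The labels do not say that the replicates were separate cultures, so the p-values measure the spread between these samples only. Each line is represented once, so a difference between pLKO and shDRG2 cells is a difference between these lines. The control carried the empty vector, so other effects of the hairpin cannot be told apart from an effect of DRG2 loss. Genes that share sequence with near copies, or exons with overlapping genes, are less certain than others, since strandedness is not stated.

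Drg2 (ENSMUSG00000020537.9, chromosome 11, 60454591 to 60468754, plus strand) was at 76.3 and 68.6 CPM in the pLKO libraries and at 8.68 and 9.34 CPM in the shDRG2 libraries. With IFN-γ it was at 72.3 and 64.3 CPM in pLKO and at 6.46 and 7.66 CPM in shDRG2 cells. The fall was 8.06-fold without IFN-γ (log2 fold change -3.01, SE 0.114, adjusted p = 1.53e-06) and 9.63-fold with IFN-γ (-3.27, SE 0.115, adjusted p = 7.80e-07). IFN-γ itself gave no called change of Drg2 in pLKO cells (-0.09, adjusted p = 0.567) or in shDRG2 cells (-0.34, adjusted p = 0.0589). That last value passed the threshold under 4 of the alternatives, for example at -0.38 with an adjusted p of 0.0377 under upper-quartile scaling. Of the 4 tested members of the list of DRG proteins and partners, Drg2 was the only one called in either knockdown comparison, and none was called after IFN-γ. The camera test of this list gave an adjusted p of 6.71e-12 without IFN-γ and 3.59e-12 with it, carried by Drg2, with a list median of -0.02 and 0.01 and a mean of -0.72 and -0.78. With an estimated correlation it gave an adjusted p of 0.0722 and an adjusted p of 0.0900, and the call with IFN-γ also ended without a filter, at 0.0606.

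The series asks how DRG2 loss bears on PD-L1, the checkpoint ligand by which tumour cells restrain T cells, and the RNA data bear on the level of its transcript, Cd274. Cd274 (ENSMUSG00000016496.7, chromosome 19, 29367455 to 29388095, plus strand) was at 10.01 ± 1.63 CPM in pLKO and 10.01 ± 0.527 CPM in shDRG2 cells without stimulation. With IFN-γ it was at 259 ± 15.6 CPM in pLKO and 296 ± 3.69 CPM in shDRG2 cells. The knockdown gave no called change without IFN-γ (-0.00, SE 0.120, 95% interval -0.27 to 0.27, adjusted p = 1.00) or with it (0.19, SE 0.0951, interval -0.02 to 0.40, adjusted p = 0.480). IFN-γ raised Cd274 25.8-fold in pLKO cells (4.69, SE 0.117, adjusted p = 6.31e-10) and 29.6-fold in shDRG2 cells (4.89, SE 0.118, adjusted p = 5.04e-10). The difference between both responses was 0.19 (interval -0.15 to 0.53, adjusted p = 1.00), which bounds it but does not show that the responses were equal.

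**Figure D1:**
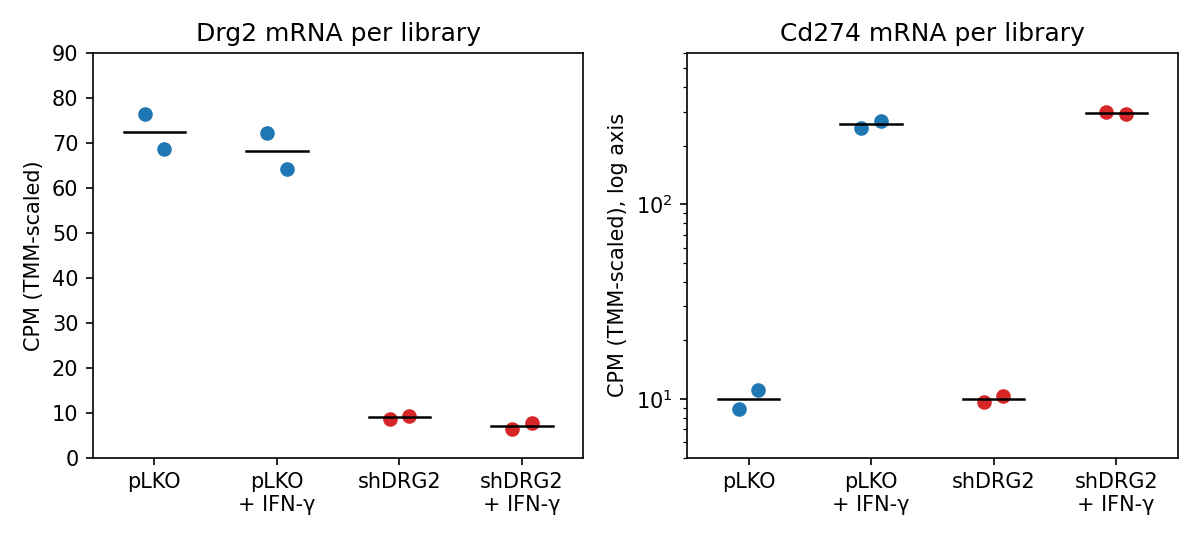
CPM of Drg2 (linear axis from 0) and Cd274 (log axis) in the 4 groups, with 1 point per library and a bar at the mean of each group. Drg2 was at 9.34 CPM or lower in every shDRG2 library and at 64.3 CPM or higher in every pLKO library, while Cd274 was at a mean of 10.01 CPM in both unstimulated groups and at 259 and 296 CPM with IFN-γ.

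Without IFN-γ, shDRG2 cells differed from pLKO cells in 162 genes, 63 higher and 99 lower. Slc16a7, a monocarboxylate transporter, rose 6.22-fold (SE 0.107 on the log2 scale, adjusted p = 1.64e-06, 7.11 to 44.2 CPM). Cck, the precursor of the peptide hormone cholecystokinin, rose 5.48-fold (SE 0.255, adjusted p = 0.00236). The chemokine gene Cxcl10, a standard interferon-induced gene, rose 2.10-fold (SE 0.0902, adjusted p = 0.000565, 40.3 to 84.8 CPM). Irf7, the transcription factor that amplifies type I interferon responses, was at least 10.5-fold lower, with 35 counts in pLKO and 0 in shDRG2 libraries (adjusted p = 0.00437).

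The other large rises were in the plasma membrane calcium pump gene Atp2b4 (1.35, SE 0.174), the microtubule-associated Map7d2 (1.27, SE 0.140), the water channel gene Aqp4 (1.16, SE 0.142), the growth hormone receptor gene Ghr (1.14, SE 0.179) and the glutathione transferase gene Gsta4 (1.05, SE 0.127). Among called genes with a mean of at least 5 CPM over the libraries, predicted genes aside, falls were largest, after Drg2, in Jmjd8 (-2.42, SE 0.196), the clock gene Arntl2 (-1.94, SE 0.205), the imprinted gene Mest (-1.31, SE 0.192), the inositol trisphosphate receptor gene Itpr2 (-1.24, SE 0.116), the transferrin gene Trf (-1.20, SE 0.154), the sorting protein gene Pacs1 (-1.09, SE 0.131) and the scaffold gene Akap12 (-1.07, SE 0.167). Stub1 on the other strand covers 35.8% of the exon bases of Jmjd8, Copg2 covers 32.9% of those of Mest, and Gm20425 covers 76.7% of those of Trf on the same strand, so reads of these genes may be shared.

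Camera placed cholesterol synthesis genes higher with the preset correlation only. Of 25 members, 2 rose and 14 rose when adjusted over the list alone, and all 25 had positive values (median 0.27). Fdps (0.44, adjusted p = 0.0443) and Idi1 (0.40, adjusted p = 0.0328), both enzymes of isoprenoid synthesis, were the called ones. Camera gave an adjusted p of 3.25e-10, and an adjusted p = 0.654 with an estimated correlation. Of 25 pigmentation genes none was called and 8 rose when adjusted over the list alone (median 0.15, camera adjusted p = 1.77e-06, adjusted p = 0.411 with an estimated correlation). Their most abundant members were Dct at -0.06 and Tyrp1 at 0.14. Of 29 p53 targets 2 fell, and 7 fell when adjusted over the list alone (median -0.14). These were Tnfrsf10b, a death receptor gene (-0.93, adjusted p = 0.00915), and Cdkn1a, the gene of the cell cycle inhibitor p21 (-0.47, adjusted p = 0.0236). Camera gave an adjusted p of 6.57e-06 for the p53 targets, and an adjusted p = 0.0722 with an estimated correlation. That correlation was -0.0234, below the preset 0.01, so the higher p-value did not come from a higher correlation. Fry gave an adjusted p of 0.295 for cholesterol synthesis genes, 0.0729 for pigmentation genes and 0.00307 for the p53 targets. Tnfrsf10b lies on chromosome 14, whose genes stood lower in shDRG2 cells as a whole (median -0.27). Without that chromosome, camera gave an adjusted p of 1.58e-05 for this list.

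In the remaining lists few members were called. Of 13 MHC class II genes 1 rose, H2-DMb1 (0.82, adjusted p = 0.0289), whose near copy H2-DMb2 covers 74.4% of its transcript. Of 52 endosome and Rab genes 1 rose, Ehd2, a membrane-remodelling ATPase (0.95, adjusted p = 0.00349). Of 25 dedifferentiation genes 1 rose, the neural crest transcription factor Sox9 (0.56, adjusted p = 0.0173), and when adjusted over the list alone 1 rose and 3 fell, with a median of 0.03 and a mean of -0.29. Of 21 immediate-early and heat shock genes 1 fell, Hspb1 (-0.57, adjusted p = 0.0480). Of 23 IFN-γ signalling genes 1 fell, Irf7, while the list median was 0.10 and its mean -0.37. Of 13 chemokine and cytokine genes 1 rose, Cxcl10, and when adjusted over the list alone 1 rose and 1 fell. Of 4 endothelial markers 1 rose, Vwf, at 1.32 CPM in pLKO and 4.96 CPM in shDRG2 cells (1.91, adjusted p = 0.0142). Camera called the endothelial markers (adjusted p = 0.00622, adjusted p = 0.654 with an estimated correlation) and the lysosomal genes (median 0.11, adjusted p = 0.0276, adjusted p = 0.967 with an estimated correlation, none of 32 called). Both calls ended without shDRG2 replicate 1, at 0.0954 and 0.852, and the lysosomal one also without pLKO replicate 2, at 0.160. No member was called among the lists of GTPases, MHC class I, type I interferon-stimulated genes, checkpoint ligands, PD-L1 trafficking, S phase, G2/M, NF-κB, unfolded protein response, hypoxia, mitochondrial fission and fusion, mitochondrial mRNAs, histones, and immune, fibroblast or epithelial markers. Adjusted over the list alone, 2 checkpoint ligands rose and 1 fell, 1 gene each fell among the unfolded protein response and mitochondrial fission and fusion lists, and 2 fibroblast markers fell. Among the most abundant members of these lists, Calr was at -0.00, Nedd4 at -0.02, Stt3b at 0.04, Mcm2 at 0.07 and Gapdh at 0.10. Of the 18 lists with no called member, 12 gained at least 1 without a filter, 8 with the replicate block and 7 with DESeq2, for example Gbp2 without a filter (adjusted p = 0.0387) and the lysosomal gene Sqstm1 with the block (adjusted p = 0.0385).

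At an unadjusted p under 0.05 there were 1723 genes, and 66 of the 162 called genes changed at least 2-fold. Of the 99 lower genes 27 lie on chromosome 14, and 127 genes were called when its genes were left out. The count rests on few libraries, being 27 without shDRG2 replicate 1, 37 without pLKO replicate 1, 61 without replicate 2 of either group and 103 without replicate 2 of shDRG2 with IFN-γ. It rose to 312 with DESeq2, 678 without a filter and 673 with the replicate number as a block, and these kept 157, 162 and 162 of the 162 genes. Of 26 named calls, 8 held in every alternative, those of Drg2, Slc16a7, Cck, Map7d2, Cxcl10, Jmjd8, Arntl2 and Itpr2. The alternatives include the threshold of 1 on the log2 fold change, which by construction no smaller change passes.

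With IFN-γ, shDRG2 cells differed from pLKO cells in 226 genes, 68 higher and 158 lower. Slc16a7 rose 7.38-fold (SE 0.137 on the log2 scale, adjusted p = 5.20e-06). Tgm2, a transglutaminase that crosslinks proteins, rose 3.53-fold (SE 0.107, adjusted p = 2.40e-05, 22.7 to 80.2 CPM). Irf7 fell by 4.84 on the log2 scale (SE 0.210, adjusted p = 7.43e-06), from 17.0 to 0.590 CPM. Gbp5, a guanylate-binding protein of antimicrobial defence, rose (0.68, SE 0.0883, adjusted p = 0.00488).

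Further rises were in Atp2b4 (1.44, SE 0.175), the secreted protein gene Scube3 (1.41, SE 0.146), the xanthine dehydrogenase gene Xdh (1.30, SE 0.212), Map7d2 (1.15, SE 0.146), Ehd2 (1.08, SE 0.109) and the perforin-like Mpeg1 (1.04, SE 0.174). Within the same limit of 5 CPM, which Irf7 does not reach, falls were largest, after Drg2, in Jmjd8 (-2.17, SE 0.192), the complement-activating protease gene Masp1 (-2.03, SE 0.264), Mest (-1.76, SE 0.202), the carbonic anhydrase gene Car6 (-1.52, SE 0.265), Trf (-1.39, SE 0.166), Kctd12 (-1.37, SE 0.164) and Itpr2 (-1.29, SE 0.115). Cxcl10 was at 0.37 with an adjusted p of 0.0677, and passed the threshold under 4 of the alternatives, at 0.0498 with library size only, 0.00178 without a filter, 0.00438 with DESeq2 and 0.0121 with the replicate block.

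Camera placed MHC class II genes higher with the preset correlation only. Of 13 members 1 rose, H2-DMb1 (0.66, adjusted p = 0.0129), 7 rose when adjusted over the list alone, and 12 had positive values (median 0.46). Camera gave an adjusted p of 2.79e-08, and an adjusted p = 0.426 with an estimated correlation. Of 32 type I interferon-stimulated genes none was called, while 30 had positive values (median 0.21), with Ifit2 at 0.46 (called without a filter, adjusted p = 2.71e-05) and Ifit3 at 0.25. Camera called this list at an adjusted p of 5.47e-06, with an adjusted p = 0.677 with an estimated correlation, and an adjusted p of 0.220 without shDRG2 IFN-γ replicate 1. Of 18 guanylate-binding and immunity-related GTPases 1 rose, Gbp5 (median 0.11, camera adjusted p = 0.00168, adjusted p = 0.677 with an estimated correlation, 0.311 without pLKO IFN-γ replicate 1). None of 25 cholesterol synthesis genes was called (median 0.17, camera adjusted p = 0.000205, adjusted p = 0.677 with an estimated correlation, 0.175 without pLKO IFN-γ replicate 2).

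Of 29 p53 targets 3 fell, Tnfrsf10b (-1.11, adjusted p = 0.00410), the TNF receptor family gene Eda2r (-0.72, adjusted p = 0.0216) and Cdkn1a (-0.42, adjusted p = 0.0305), and 4 fell when adjusted over the list alone (median -0.10). Camera gave an adjusted p of 0.000205, an adjusted p = 0.133 with an estimated correlation, and an adjusted p of 0.000775 without the genes of chromosome 14, where Tnfrsf10b lies. The estimated correlation was -0.0230, again below the preset 0.01, so here too the higher p-value did not come from a higher correlation. Fry gave an adjusted p of 0.00377 for the p53 targets and 0.171 for the dedifferentiation genes. Of 25 dedifferentiation genes 1 fell, Thbs1, the gene of the matrix protein thrombospondin (-1.29, adjusted p = 0.0232), and when adjusted over the list alone 2 rose and 7 fell (median -0.28). Camera called this list at an adjusted p of 0.00327, with an adjusted p = 0.617 with an estimated correlation and 0.119 without pLKO IFN-γ replicate 1. Of 25 pigmentation genes 1 fell, the dopachrome tautomerase gene Dct (-0.47, adjusted p = 0.0254), and 3 fell when adjusted over the list alone. Of 33 stress response genes 1 fell, the chaperone gene Dnajc3 on chromosome 14 (-0.45, adjusted p = 0.0122). Of 33 hypoxia and glycolysis genes 1 fell, the aldolase gene Aldoc (-2.43, adjusted p = 0.0347), although the list median was 0.18 and camera placed the list higher (adjusted p = 0.0171, adjusted p = 0.677 with an estimated correlation). That call ended without pLKO IFN-γ replicate 1, at 0.180, and without shDRG2 IFN-γ replicate 1, at 0.523. Of 16 checkpoint ligands 1 fell, the galectin gene Lgals3 on chromosome 14, with 95 counts in pLKO and 0 in shDRG2 libraries (adjusted p = 0.00748), while the list median was 0.16 and its mean -0.42. Aldoc and Lgals3 average under 1 CPM and were named after their values were seen. Of 23 IFN-γ signalling genes 1 fell, Irf7, with a list median of 0.13 and a mean of -0.10, and of 52 endosome and Rab genes 1 rose, Ehd2. No member of the other lists was called, among them MHC class I, chemokines, PD-L1 trafficking, lysosomes, both cell cycle lists, NF-κB targets, mitochondrial mRNAs, histones and markers of other cells. Adjusted over the list alone, 1 IFN-γ signalling gene rose and 1 fell, 1 chemokine gene rose and 1 fell, 1 checkpoint ligand rose and 1 fell, 2 stress response genes rose and 1 fell, 2 hypoxia genes fell, 1 mitochondrial fission gene fell and 2 endothelial markers rose. Of the 17 lists with no called member, 8 gained at least 1 without a filter, 7 with the replicate block and 2 with DESeq2. Sqstm1 was called with the block (adjusted p = 0.0139) and without a filter (0.00909), and Mki67 of the G2/M list without a filter (0.00410).

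At an unadjusted p under 0.05 there were 1616 genes, and 87 of the 226 called genes changed at least 2-fold. Of the 158 lower genes 42 lie on chromosome 14, and 160 genes were called when its genes were left out. The count was 44 without shDRG2 IFN-γ replicate 1, 58 without its replicate 2, 86 without pLKO IFN-γ replicate 1, 123 without its replicate 2 and 124 with only the 4 libraries compared. It rose to 653 without a filter and 675 with the replicate block, and both kept all 226 genes. Of 25 named calls, 13 held in every alternative, those of Drg2, Slc16a7, Tgm2, Atp2b4, Scube3, Map7d2, Ehd2, Jmjd8, Mest, Trf, Kctd12, Itpr2 and Irf7. Here too, changes smaller than 1 on the log2 scale could not hold, given the added threshold.

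The knockdown comparisons with and without IFN-γ share no library. They compare the same pLKO and shDRG2 lines, however, and take their spread from the same fit. The numbers given by independent calls are thus a reference only and no measure of replication. Of the genes higher in shDRG2 cells, 36 were called in both, against 0.317 given by independent calls, and of the lower genes 68 were called in both, against 1.16. Slc16a7, Atp2b4, Map7d2 and Ehd2 were among the shared rises, and Drg2, Irf7, Jmjd8, Mest, Trf, Itpr2, Tnfrsf10b and Cdkn1a among the shared falls. Across the 13500 genes, which are not independent replicates, Pearson's r between the effects was 0.531 and Spearman's rho 0.480. Over all 13500 genes 69.1% had the same sign in both effects. Over the 162 genes called without IFN-γ, 98.8% had the same sign with IFN-γ. Of the 68 genes lower in both, 19 lie on chromosome 14, among them Tnfrsf10b, Supt16, Xpo7 and Pdhb. Leaving out 1 library moved the number of shared calls, 104 in all, to between 22 without untreated shDRG2 replicate 1 and 71 without pLKO IFN-γ replicate 2, and Pearson's r was lowest without untreated shDRG2 replicate 1, at 0.349. These runs filtered the genes anew and tested between 13861 and 13943, so their r is not over the same genes as in the main analysis.

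Genes of chromosome 14 stood lower in shDRG2 cells along the whole chromosome. The median log2 fold change of its 302 genes of at least 10 CPM was -0.27 without and -0.27 with IFN-γ. The medians of the other autosomes lay between -0.02 and 0.06 without IFN-γ and between -0.04 and 0.06 with it. In 4 consecutive parts of the chromosome the median was -0.30, -0.26, -0.25 and -0.26 without IFN-γ. Chromosome 14 took 2.66% to 2.78% of the CPM in the 4 pLKO libraries and 2.25% to 2.30% in the 4 shDRG2 libraries. It holds 436 of the 13500 tested genes, so its share of the lower calls was 8.44 times the expected one without IFN-γ and 8.23 times with it. Chromosome 14 was singled out after these values were seen, so no p-value is given. Of the higher calls 2 of 63 and 3 of 68 lie on this chromosome.

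**Figure D2:**
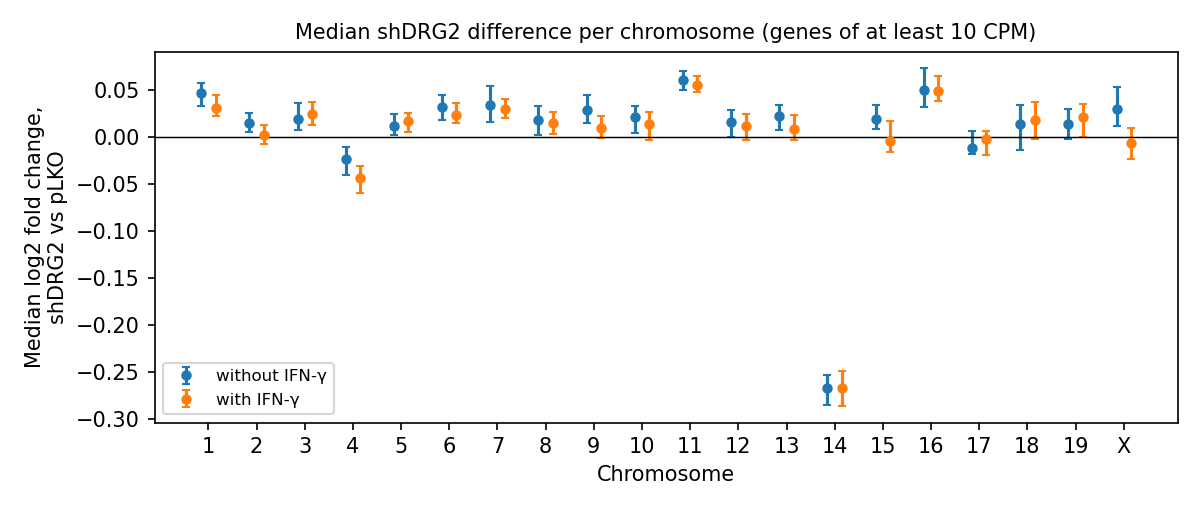
Median log2 fold change of shDRG2 against pLKO cells for the genes of each chromosome with at least 10 CPM, without and with IFN-γ, with 95% bootstrap intervals over genes. Chromosome 14 lies at -0.27 in both, and the other autosomes lie between -0.04 and 0.06.

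IFN-γ changed 3796 genes in pLKO cells, 2082 higher and 1714 lower, and 4233 genes in shDRG2 cells, 2182 higher and 2051 lower. Which direction held the majority depended on the scaling. With upper-quartile factors there were 1855 higher and 2129 lower genes in pLKO and 1950 and 2416 in shDRG2 cells. The rises named next are among the largest of genes with a mean of at least 5 CPM, predicted genes aside. In pLKO cells H2-Aa, an MHC class II chain, was at least 1189-fold higher, Gbp9, Gbp11 and Gbp8 were at least 847-fold, 807-fold and 706-fold higher, and Tgtp1 rose by 13.44 on the log2 scale (SE 0.199, adjusted p = 2.13e-11). In shDRG2 cells Mpeg1 was at least 1106-fold higher, Gvin1 at least 896-fold, Slamf8 at least 668-fold and Ly6a at least 645-fold. Many pigmentation and cell cycle genes fell in both lines, although camera with an estimated correlation called none of these lists.

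Other large rises in pLKO cells were Gvin1 (at least 652-fold), Mpeg1 (at least 613-fold) and Apol6 (ratio 8383, interval 2868 to 40654). In shDRG2 cells they were Gbp10 (12.80, SE 0.306), Iigp1 (12.59, SE 0.190) and the caspase gene Casp12 (at least 421-fold). Tgtp1, Gvin1 and Gbp10 have near-identical copies. Among called genes with a mean of at least 5 CPM, predicted genes aside, falls were largest in the lipid transporter gene Abca12 (-3.52, SE 0.145 in pLKO and -4.27, SE 0.151 in shDRG2 cells), Cck (-3.42, SE 0.373 and -4.95, SE 0.313), the heparan sulphate enzyme gene Hs3st1 (-2.53 and -3.66), Car6 (-2.55 and -3.44), Spsb4 (-2.67 and -3.38), the transcription factor gene Etv5 (-2.88 and -2.81) and the orphan nuclear receptor gene Nr4a1 (-2.68 and -2.70). Ttn in pLKO cells (-2.54, SE 0.337) and the monoacylglycerol lipase gene Mgll in shDRG2 cells (-2.73, SE 0.161) were also among them.

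The interferon lists rose almost in full. Of 18 guanylate-binding and immunity-related GTPases all rose in both lines, with a median of 11.49 in pLKO and 10.81 in shDRG2 cells, or 10.02 and 10.61 with genes at 0 set to their bound. All 32 type I interferon-stimulated genes rose in both lines, with the nucleic acid sensor gene Zbp1 at 11.19 and 11.51 and Oasl2 at 7.18 and 7.56. Oas3 rose by 8.62 in pLKO cells and by a ratio of 2020 (interval 559 to 16684) in shDRG2 cells, and Ifi44 by 7.93 and 9.07. Of 23 IFN-γ signalling genes 18 rose and 1 fell in each line. Ciita, the master regulator of MHC class II, rose by a ratio of 5986 (interval 1074 to 236472) and of 6922 (interval 1242 to 273421). Irf8 rose by 10.41 in pLKO cells and by a ratio of 4127 (interval 1412 to 20015) in shDRG2 cells, and Batf2 by 9.56 and by a ratio of 1717 (interval 587 to 8329). The feedback inhibitor gene Socs1 rose by 6.54 in pLKO cells, and Irf7 was at least 11.3-fold higher in shDRG2 cells. Camera called these lists in both lines, also with an estimated correlation. The adjusted p with an estimated correlation was 0.00307 and 0.00186 for the GTPases, 0.0364 and 0.0294 for the interferon-stimulated genes, and 0.00806 and 0.00870 for IFN-γ signalling.

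Antigen presentation rose with them. Of 21 MHC class I genes 18 rose in each line, with the immunoproteasome genes Psmb8 at 9.93 in pLKO and 11.72 in shDRG2 cells and Psmb9 at 9.57 and 10.54, and the class I gene H2-T23 at 8.32 and 7.54. H2-Q4 was at least 106-fold higher in pLKO cells and rose by a ratio of 210 (interval 37.3 to 8322) in shDRG2 cells. Of 13 MHC class II genes 9 rose and 1 fell in pLKO cells, and 10 rose and 1 fell in shDRG2 cells. The invariant chain gene Cd74 rose by 11.86 and 12.13, H2-Ab1 by ratios of 2108 (interval 583 to 17412) and 5528 (interval 992 to 218365), and H2-Eb1 by a ratio of 5762 (interval 1034 to 227616) in shDRG2 cells. The adjusted p with an estimated correlation was 0.00489 and 0.00186 for class I and 0.0447 and 0.0294 for class II. Of 13 chemokine and cytokine genes 10 rose and 1 fell in each line. The T cell attractant genes Cxcl9, Cxcl10 and Cxcl11 were among them. Cxcl9 rose by ratios of 1444 (interval 399 to 11932) and 1997 (interval 553 to 16497), Cxcl10 by 4.22 and 3.51, and Cxcl11 by a ratio of 104 (interval 28.4 to 864) and by 5.15. The death ligand gene Tnfsf10 rose by 7.64 and 7.98. Camera gave this list adjusted p-values of 9.67e-09 and 4.10e-08, with an adjusted p = 0.0524 and an adjusted p = 0.0511 with an estimated correlation.

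**Figure D3:**
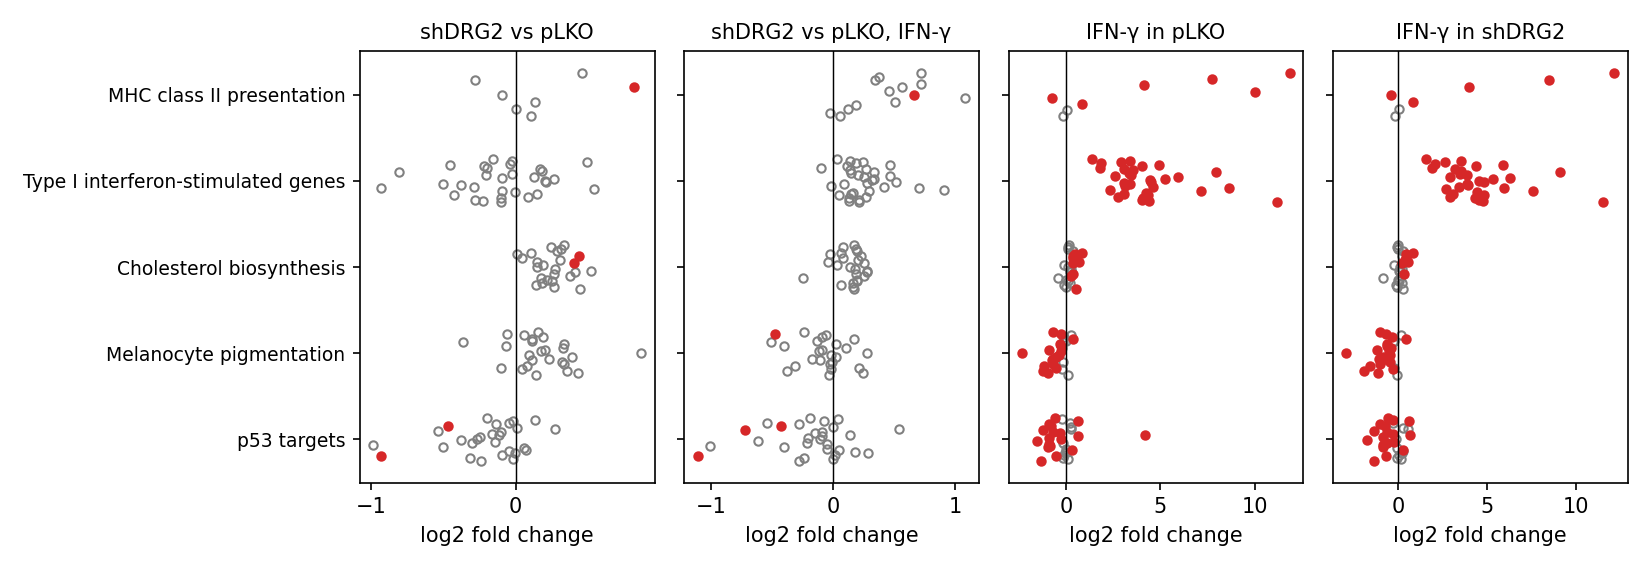
Log2 fold changes of the members of selected gene lists in the 4 comparisons of groups, with 1 point per gene, filled where the gene was called and open where it was not, leaving out members with 3 counts or fewer in a compared group. Of 13 MHC class II genes 7, 13, 8 and 7 are drawn in the knockdown comparisons without and with IFN-γ and in the IFN-γ comparisons of pLKO and shDRG2 cells.

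Among 16 checkpoint and co-signalling ligands 6 rose and 1 fell in pLKO cells, and 5 rose and 2 fell in shDRG2 cells. Cd274 was among the rises, with the co-signalling receptor gene Tnfrsf14 (5.78 and 3.79), the do-not-eat-me signal Cd47 (2.01 and 2.13) and, in shDRG2 cells, the galectin gene Lgals9 (0.97). The NKG2D ligand gene Ulbp1 fell in pLKO cells (-1.25, SE 0.210, adjusted p = 0.00134). Camera gave adjusted p-values of 0.00179 and 0.00811, with an adjusted p = 0.222 and an adjusted p = 0.257 with an estimated correlation, and the call in shDRG2 cells also ended without a filter, at 0.0633. Of 32 PD-L1 trafficking and turnover genes 6 rose and 6 fell in pLKO cells, and 4 rose and 5 fell in shDRG2 cells (camera adjusted p = 0.671 and 0.679). The glycosyltransferase gene B3gnt3 (1.74 and 1.78) and Cmtm6, whose product keeps PD-L1 on the surface (0.55 and 0.79), rose, while Hip1r (-0.67 and -0.73), an adaptor that sends PD-L1 to lysosomes, and the sorting receptor gene Sort1 (-0.65 and -0.79) fell. Of 52 endosome and Rab genes 11 rose and 9 fell in pLKO cells, and 13 rose and 7 fell in shDRG2 cells (camera adjusted p = 0.938 and 0.932). Rab5c (1.00 and 0.98) and Rab21 (0.56 and 0.70) rose, and Mical1 (-0.79 and -0.76) and Rin2 (-0.74 and -0.70) fell. Of 32 lysosomal genes 14 rose and 1 fell in pLKO cells, and 11 rose and 3 fell in shDRG2 cells, with Ctsh (1.22 and 1.02), Grn (0.98 and 1.03), Gla (1.02 and 1.01) and Scarb2 (0.73 and 0.65) highest (camera adjusted p = 0.139 and 0.394).

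Of 25 pigmentation genes 16 fell and 1 rose in pLKO cells, and 19 fell and 1 rose in shDRG2 cells. The melanosomal transporter genes Oca2 (-2.34 and -2.93) and Slc45a2 (-1.20 and -1.59) and the channel gene Trpm1 (-1.23 and -1.96) fell in both, Tyr, the gene of tyrosinase, fell in pLKO cells (-0.96) and Mlph in shDRG2 cells (-1.20). Camera gave adjusted p-values of 2.61e-05 and 3.21e-10, with an adjusted p = 0.222 and an adjusted p = 0.0961 with an estimated correlation. Of 25 dedifferentiation genes 6 rose and 7 fell in pLKO cells, and 5 rose and 8 fell in shDRG2 cells (camera adjusted p = 0.623 and 0.200). In pLKO cells this list had a median of -0.21 and a mean of 0.02. The fibronectin gene Fn1 (1.65 and 2.13) rose in both and the integrin gene Itgb3 (-1.64 and -1.98) fell in both. Thbs1 (2.01) and the receptor kinase gene Axl (1.33) rose in pLKO cells, and the matrix genes Ctgf (-2.16) and Sparc (-1.05) fell in shDRG2 cells.

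Of 36 S-phase genes 16 fell in pLKO and 22 in shDRG2 cells, and of 41 G2/M genes 23 and 30 fell, with no rise in either list. Examples are E2f8 (-0.62 and -0.64), Ccne2 (-0.60 and -0.61) and Cdc6 (-0.56 and -0.70) for S phase, Tipin (-0.56) in pLKO and Tyms (-0.63) in shDRG2 cells. For G2/M they are Gtse1 (-0.90 and -0.85), Cdc25b (-0.77 and -0.85), the proliferation marker gene Mki67 (-0.72 and -1.21) and Cenpa (-0.57 and -0.76). Camera gave adjusted p-values of 0.00126 and 0.000239 for S phase and of 0.000270 and 1.10e-05 for G2/M. With an estimated correlation both lists had an adjusted p = 0.978 in pLKO and an adjusted p = 0.816 in shDRG2 cells. Of 29 p53 targets 14 fell and 4 rose in pLKO cells, and 15 fell and 4 rose in shDRG2 cells, led by Perp (-1.53 and -1.77), Zmat3 (-1.32 and -1.36), Eda2r (-1.20 and -1.39), Plk3 in pLKO (-0.98) and Ccng1 in shDRG2 cells (-1.06). Camera gave 0.00241 and 0.00862, with an adjusted p = 0.0805 and an adjusted p = 0.103 with an estimated correlation.

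Of 33 genes of the unfolded protein and integrated stress response 9 rose and 4 fell in pLKO cells, and 12 rose and 5 fell in shDRG2 cells. The stress-induced transcription factor genes Atf3 (2.59 and 3.20) and Cebpb (1.43 and 1.54), the chromatin regulator gene Nupr1 (2.11 and 2.19) and the folate enzyme gene Aldh1l2 (0.79 and 1.15) rose most (camera adjusted p = 0.623 and 0.361). Of 21 immediate-early and heat shock genes 5 rose and 6 fell in each line. Egr1 (-2.55 and -3.33) and Nr4a1 fell, and Zfp36 (1.89 and 2.00) and Hspb1 (1.52 and 1.92) rose (camera adjusted p = 0.961 and 0.932). Of 19 NF-κB targets 5 rose and 2 fell, and 7 rose and 1 fell, with the apoptosis inhibitor genes Birc3 (1.03 and 1.36) and Birc2 (0.94 and 0.94) and Tnfaip2 (0.61 and 0.89) higher, Map3k8 higher in shDRG2 cells (0.94) and Rel lower in pLKO cells (-0.40) (camera adjusted p = 0.938 and 0.679).

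Of 25 cholesterol synthesis genes 10 rose in pLKO and 7 in shDRG2 cells and none fell, with Ebp (0.85 and 0.81), Hsd17b7 (0.70 and 0.51) and Fdft1 (0.46 and 0.43) in both, and Tm7sf2 in pLKO (0.50) (camera adjusted p = 0.234 and 0.679). Of 33 hypoxia and glycolysis genes 2 rose and 2 fell in pLKO cells, and 3 rose and 4 fell in shDRG2 cells (0.630 and 0.699). P4ha1 (0.45 and 0.63) rose and Egln1 (-0.55 and -0.67) fell in both, with Kdm3a (0.42) and Hk1 (-0.44) in pLKO and P4ha2 (-0.74) and Ndrg1 (-0.56) in shDRG2 cells. Of 13 mitochondrially encoded mRNAs 3 fell in pLKO and 6 in shDRG2 cells, with mt-Cytb at -0.40 and -0.69 and mt-Nd1 at -0.39 and -0.57. mt-Nd4l fell in pLKO cells (-0.45), and mt-Nd5 (-0.58) and mt-Nd4 (-0.55) in shDRG2 cells. Camera gave 0.184 and 0.0249, the second with an adjusted p = 0.816 with an estimated correlation and 0.0695 without shDRG2 IFN-γ replicate 2. Of 13 mitochondrial fission and fusion genes 2 rose and 1 fell, and 1 rose and 1 fell, with Yme1l1 (0.30 and 0.28) higher, Mtfp1 (-0.46 and -0.48) lower and Fis1 (0.26) higher in pLKO cells. Of 7 replication-dependent histone genes 1 rose, Hist1h1c (0.94 and 1.22).

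Of 2 immune markers tested 1 rose in each line, Cd14 (1.82 and 1.70). Of 7 fibroblast markers 2 rose and 2 fell in pLKO cells, and 3 rose and 2 fell in shDRG2 cells. The list median was -0.06 and -0.22 and its mean 1.23 and 1.70. Acta2 was at least 61.7-fold and at least 49.3-fold higher, Col6a3 rose by 1.80 and 4.68, and Col1a2 (-1.82 and -2.19) and Pdgfrb (-0.46 and -0.39) fell. Of 4 endothelial markers 1 rose and 3 fell, and 1 rose and 2 fell, with Vwf (-1.70 and -3.88) and Egfl7 (-0.74 and -0.67) lower, and in pLKO cells a median of -1.22 and a mean of 0.59. The 1 epithelial marker tested, Cdh1, was at -0.45 in pLKO cells (not called) and fell by 1.55 in shDRG2 cells. Cd14 and Cdh1 average under 1 CPM and were named after their values were seen.

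Adjusted over the list alone, the rises and falls in pLKO cells were 19 and 1 for IFN-γ signalling, 10 and 1 for MHC class II, 10 and 2 for chemokines, 6 and 7 for PD-L1 trafficking, 14 and 9 for endosomes, 15 and 1 for lysosomes, 2 and 17 for pigmentation, 0 and 21 for S phase, 0 and 28 for G2/M, 4 and 15 for p53 targets, 5 and 3 for NF-κB, 11 and 5 for the stress response, 1 and 1 for hypoxia, 12 and 0 for cholesterol synthesis, 0 and 2 for mitochondrial mRNAs and 6 and 7 for immediate-early and heat shock genes. In shDRG2 cells they were 10 and 2 for MHC class II, 14 and 7 for endosomes, 1 and 20 for pigmentation, 6 and 10 for dedifferentiation, 0 and 28 for S phase, 0 and 33 for G2/M, 13 and 6 for the stress response, 3 and 2 for hypoxia, 0 and 9 for mitochondrial mRNAs and 3 and 3 for fibroblast markers. The other lists had the same counts either way.

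Of the called genes 1096 in pLKO and 1269 in shDRG2 cells changed at least 2-fold, and the smallest called change was 0.21 in each. The counts were 2482 in pLKO cells without pLKO replicate 1, 2495 without pLKO IFN-γ replicate 2, and 2720 in shDRG2 cells without shDRG2 IFN-γ replicate 1. Of the named calls, 61 of 102 and 68 of 103 held in every alternative. Called changes under 1 on the log2 scale failed the added threshold of 1 by construction. That threshold ended 88 named calls over all comparisons, so these shares reflect the size of the changes as well as their stability.

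The responses of both lines to IFN-γ were similar. Both lines shared 1766 rises, against 337 given by independent calls, and 1485 falls, against 260, and 1 gene moved in opposite directions. The calls of both lines come from the same fit, so they are not independent. Only in shDRG2 cells 416 rises and 566 falls were called, and only in pLKO cells 316 and 229. Over the 3796 genes changed in pLKO cells Pearson's r across genes was 0.951, Spearman's rho 0.968 and the slope of the shDRG2 on the pLKO response 0.993. Over the 3600 of them with more than 3 counts in every group, a choice made after seeing the data, r was 0.982 and the slope 1.04. Regressing the pLKO on the shDRG2 response over the 4036 genes changed in shDRG2 cells with more than 3 counts in every group gave 0.898, which differs from the slopes above in both the genes and the direction of the regression. On simulated data with a true slope of 1 the fitted slope was 0.955, over 1559 genes called in pLKO cells. That fit had no limit on counts, so it is a reference for the slope of 0.993 only. Its changes were drawn at random and not taken from these data.

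**Figure D4:**
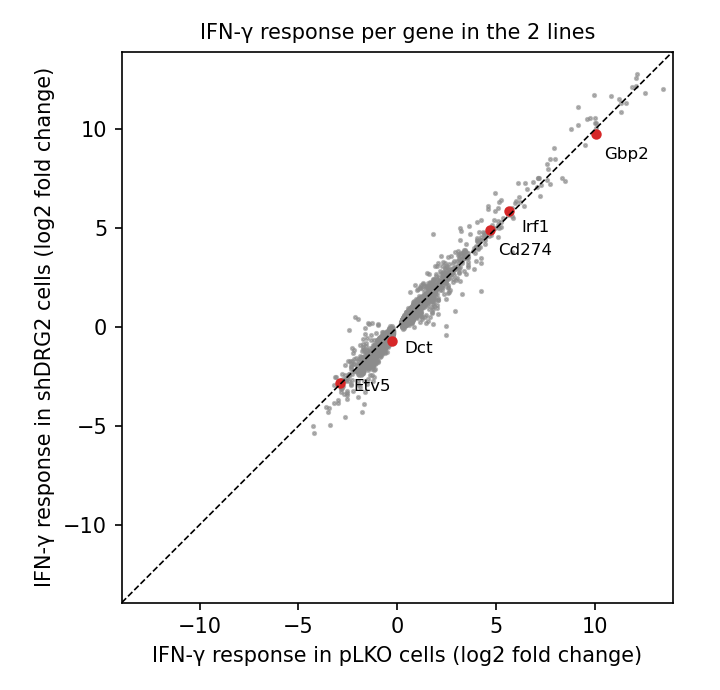
Log2 fold change after IFN-γ in shDRG2 cells against that in pLKO cells for the 3600 genes changed in pLKO cells with more than 3 counts in every group, with 5 genes labelled. The points follow the dashed line of equal response (slope 1.04, r 0.982).

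The difference between the responses was called for 1 gene of 13500, Gm8226, a processed pseudogene of the ribosomal protein gene Rpl7a (fitted 9.97, SE 0.768, adjusted p = 0.00478). It had 5.29 and 4.75 CPM in pLKO, 0 in both pLKO libraries with IFN-γ, 11.4 and 12.2 CPM in shDRG2 and 11.4 and 7.58 CPM in shDRG2 libraries with IFN-γ. Given the libraries at 0, the fitted value is no bound and its SE does not measure its error. It is a predicted gene and was named after its values were seen. Summed with its pseudogene copies the difference was 0.03 (SE 0.183). At an unadjusted p under 0.05 there were 321 genes, and DESeq2 called 9. No member of any list was called, but 6 of the 28 lists gained at least 1 without a filter and 2 with DESeq2. Cxcl10 rose less in shDRG2 cells by 0.70 (SE 0.124, unadjusted p = 0.000194, adjusted p = 0.656), and this passed the threshold at 0.00206 with DESeq2 and 0.000126 without a filter. Adjusted over the list alone it had the 1 lower value among chemokines, while 1 fibroblast marker was higher and 1 endothelial marker lower. Camera placed 7 lists apart, of which none held with an estimated correlation. Type I interferon-stimulated genes rose more in shDRG2 than in pLKO cells by this test, with 29 of 32 positive (median difference 0.31, adjusted p = 5.68e-12, adjusted p = 0.744 with an estimated correlation). Pigmentation genes fell more, with 2 of 25 positive (median -0.29, adjusted p = 7.91e-19, adjusted p = 0.183 with an estimated correlation), and 6 were lower when adjusted over the list alone. The other 5 were dedifferentiation (median -0.20, adjusted p = 0.00369, adjusted p = 0.744 with an estimated correlation), G2/M (-0.09, 0.00149, and 0.905 with an estimated correlation), mitochondrial mRNAs (-0.19, 0.00149, and 0.748), cholesterol synthesis (-0.10, 0.00920, and 0.905) and NF-κB targets (0.07, 0.0278, and 0.643). Each of these 5 calls ended without at least 1 of the libraries, for example at 0.130, 0.708, 0.721, 0.238 and 0.273 without pLKO replicate 2. The cholesterol synthesis result turned its direction without pLKO IFN-γ replicate 1 (0.990) and without untreated shDRG2 replicate 1 (0.905), and that of G2/M without shDRG2 IFN-γ replicate 1 (0.299).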

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

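The test of pooled copies of Gm8226 was chosen only after its result was seen. Flagged were 8 results past the threshold for a difference between the IFN-γ responses of the lines, and 1 signal in data left out of the comparisons. Of the 8, 7 are list calls by camera with the preset correlation, and none of those held with an estimated one.

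Gm8226, a pseudogene of Rpl7a, had a fitted difference between responses of 9.97 (SE 0.768, adjusted p = 0.00478, edgeR quasi-likelihood test), the 1 called gene of 13500. In the pLKO libraries with IFN-γ it had 0 CPM while the copy Rpl7a-ps11 had 10.2 and 9.65 CPM, and in the shDRG2 libraries Rpl7a-ps11 had 0 to 3.67 CPM while Gm8226 had 7.58 to 12.2 CPM. Summed over Gm8226 and its 21 pseudogene copies, without Rpl7a, the difference was 0.0251 (SE 0.183), which argues against a change in their joint level. Reads shared between near-identical copies may be the source, assigned to different copies in different libraries, but an earlier form of this test that included Rpl7a could not have come out otherwise and was replaced. A true switch between the copies stays open, since no read was examined.

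Type I interferon-stimulated genes had a median difference between responses of 0.31, shDRG2 minus pLKO, by camera with the preset correlation. Pigmentation genes had a median difference of -0.29 by the same test. The median differences of the other lists past the threshold were -0.20 for dedifferentiation genes, -0.0864 for G2/M genes, 0.0700 for NF-κB targets, -0.10 for cholesterol synthesis genes and -0.19 for mitochondrially encoded mRNAs. With an estimated correlation none of these 7 was past the threshold, with adjusted p-values from 0.183 for pigmentation to 0.905 for G2/M and cholesterol synthesis.

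Of the 27 entries whose gene names had turned into dates, 20 held more than 3 counts in all, and they were not analysed here.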

How the results depend on the processing

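The tests without the genes of chromosome 14, which left 127 and 160 knockdown calls, and of the slope over genes above 3 counts were chosen after seeing the data. Under RLE, upper-quartile and library-size scaling and limma-voom, all counts of changed genes stayed within 1.5 times the reported ones, and no scaling moved the median of all genes by over 0.1. The majority of changes after IFN-γ still turned from rises to falls in both lines under upper-quartile and library-size scaling. With library size only there were 1840 higher and 2054 lower genes in pLKO and 2005 and 2267 in shDRG2 cells. Cd274 kept its side of the threshold in all 5 comparisons and Drg2 in 4, under every alternative run. The Drg2 change after IFN-γ in shDRG2 cells passed the threshold at -0.38 with upper-quartile scaling, -0.37 with library size only, -0.33 without a filter and -0.34 with the replicate block. Without a filter, 678 and 653 genes differed in the knockdown without and with IFN-γ, 58 in the difference between responses, 324 were shared between the knockdown comparisons, and the knockdown effects correlated at 0.137 (Pearson) and 0.239 (Spearman); with at least 1 CPM in 4 libraries Pearson's r was 0.674. DESeq2 called 312 genes without IFN-γ, 9 for the difference and 176 shared. A log2 threshold of 1, which by construction removes smaller changes, left 66, 87, 1096 and 1269 genes in the 4 comparisons of groups, and 45 shared. With only the 4 libraries compared, 124 genes differed with IFN-γ, 63 were shared and Pearson's r was 0.677. Apart from the threshold of 1, the cause was not tested.

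With the replicate number as a block, 673 and 675 genes differed in the knockdown comparisons, 5166 and 5634 after IFN-γ, 2 in the difference and 354 were shared, and all 162 and 226 reported knockdown calls were among them. Over the 140 counts of called list members, 38 moved with the block, 46 without a filter and 26 with DESeq2. The labels do not pair the samples, and the model without a block was fixed before the data were examined. The departures of replicate 1 from replicate 2 correlated across genes at 0.278 and 0.242 between the groups of the knockdown comparisons and at 0.566 and 0.417 between those of the IFN-γ comparisons, and the third principal component parted replicate 1 from replicate 2 in each group. Untreated pLKO and IFN-γ shDRG2 departures correlated at 0.0968, and IFN-γ pLKO and untreated shDRG2 departures at 0.420. The values thus hold a difference shared, to an uneven degree, by equal replicate numbers. The reported counts leave it in the residual spread, and its source was not tested.

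Leaving out 1 library, which leaves a lone sample assumed to vary like the other groups, gave 27 to 167 genes in the knockdown without IFN-γ, 44 to 202 with it, 2482 to 3749 and 2720 to 4297 after IFN-γ, 1 to 2 for the difference and 22 to 71 shared, with Pearson's r from 0.349 to 0.448 and Spearman's rho from 0.336 to 0.459. The camera result for cholesterol synthesis in the difference turned its direction without pLKO IFN-γ replicate 1 (adjusted p = 0.990) and without untreated shDRG2 replicate 1 (0.905), over a range from 1.22e-07, and that for G2/M without shDRG2 IFN-γ replicate 1 (0.299), over 2.16e-17 to 0.708; the cause was not tested. Camera with an estimated correlation ended 34 of the camera calls over 140 tests of lists. For the p53 targets in both knockdown comparisons it did so at correlations of -0.0234 and -0.0230, below the preset 0.01. Losses under this setting are thus not all due to a higher correlation. The self-contained test fry ended 19 of the camera calls and added 4. With 2 libraries per group, 50.5% to 60% of 1.5-fold changes between groups were recovered on simulated counts, so a gene not called is not shown to be unchanged. Each simulation changed far fewer genes than IFN-γ did and held no difference between replicate numbers. These shares are thus no estimate for the IFN-γ comparisons.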

Other observations

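No test in this part was chosen after its own result was seen, but each addresses a pattern already seen in these data, and the genes named were picked after their values were seen.

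Several genes that report output of the ERK kinase pathway fell after IFN-γ in both lines. Of 15 tested genes of a list written without Etv5 and Spry2, which had been seen first, 8 fell and 2 rose in each line. Egr1 (-2.55 and -3.33), reported above with the immediate-early genes, is 1 of the falls, so the list was not free of genes already reported. The transcription factor gene Etv4 fell by 3.48 on the log2 scale in pLKO and by 4.09 in shDRG2 cells, and the feedback inhibitor genes Spry4 (-3.59 and -4.07) and Spred2 (-1.61 and -1.81) and the cyclin gene Ccnd1 (-0.81 and -0.85) fell too. The phosphatase gene Dusp6, also a direct ERK target, rose (0.78 and 1.18), as did Myc in shDRG2 cells. Bcl2l11, which ERK signalling lowers, rose in pLKO cells (0.39), and the list did not reverse its sign. The median was -0.81 in pLKO and -0.62 in shDRG2 cells. Lower ERK output may account for this, but camera, at p = 0.000867 and p = 0.00288 with the preset correlation, gave p = 0.0684 and p = 0.101 with an estimated one, and Dusp6 went the other way, so the test leaves it undecided.

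A set of genes expressed in pLKO cells was almost silent in shDRG2 cells with and without IFN-γ. Among them were Pycard, the inflammasome adaptor gene, at 12.7 CPM in pLKO and 0.0303 CPM in shDRG2 cells with IFN-γ, Usp29 (at least 57.9-fold lower without IFN-γ), Arhgap32 (at least 35.2-fold), Ubqln2 (at least 28.7-fold) and Zfp503 on chromosome 14 (at least 39.1-fold). There were 10 such genes, which fell by over 3 on the log2 scale in both treatments from at least 1 CPM. Of these, 0 had a copy with 95% identity over 50% of the transcript, which argues against reads moved to such a copy. Only 3830403N18Rik had a copy over at least 20% of its transcript, with Xlr at 48.4% and Gm14599 at 35.1%. The 20 nearest tested neighbours had a median of -0.10 without and -0.07 with IFN-γ, which argues against deletions spanning neighbours as the general source. Xlr beside 3830403N18Rik was at -1.32 and -2.66, but its reads may be shared with that gene. Loss or silencing of single genes in the shDRG2 line, an effect of DRG2 loss and another effect of the hairpin stay open, since each line is represented once.

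Genes of chromosome 14 stood lower in shDRG2 cells, with a median log2 fold change of -0.27 in both treatments. After removing the trend on GC content and transcript length the medians were -0.29 and -0.28, which argues against that bias. Another 76 genes of 1 to 10 CPM lay outside the set of at least 10 CPM but came from the same libraries. Their median was between -0.29 and -0.22 in either treatment and either part of the chromosome, while other autosomes had a median of -0.01. Some of them, such as Pnma2 and Zfp503, were already among the lower calls. This extends the shift to genes of lower expression but cannot tell a lower dosage from another shift of the whole chromosome. The values are consistent with a lower dosage of chromosome 14 in the shDRG2 line or in part of its cells, a hypothesis that no DNA measurement here can test. Whether it bears on single genes such as Tnfrsf10b or Zfp503 is also open.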
